A study of Mus musculus with 9 samples.

How the data were processed

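Single-cell RNA sequencing of mouse liver was carried out on dissociated cells barcoded in microwells on the Singleron GEXSCOPE platform, in which the poly-A end of each transcript is tagged with a unique molecular identifier (UMI) so that copies made by PCR are counted once. Per the labels, livers of C57BL/6J mice were digested with enzymes, red blood cells were lysed, and libraries were sequenced on a NovaSeq instrument. Carbon tetrachloride (CCl4), a hepatotoxin whose repeated injection scars the liver, was given to wild-type mice for 0, 2 or 4 weeks, and mice labelled CluKO also received recombinant human clusterin. The 9 samples fall into 4 groups. Each wild-type time point is 1 sample, and the 6 samples labelled CluKO are held in 1 matrix whose cell barcodes carry no sample name, so that matrix was treated as 1 pooled sample.

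The deposited values are raw UMI counts per row and cell in 4 sparse matrices, and the counts were checked to be whole numbers. The genome build was GRCm38, per the submitters' processing notes. The aligner, the counting program and the rule by which barcodes were taken as cells are not given in the sources used here. A gene table of 53713 lines pairs Ensembl identifiers with symbols and has the row count of the matrix labelled CluKO. The 3 wild-type matrices have 26734, 22947 and 25021 rows, and the files used here do not pair these rows with gene names. Their rows were left unnamed, and depth and genes per cell are the values given for them. The planned comparisons of gene levels, gene lists and cell classes between wild-type time points, and between CluKO and wild type, were therefore not analysed here. Of the 556 marker and list genes fixed beforehand, 552 were found in the gene table. Hba-a1, Hba-a2, C5 and Ccn2 were not found under those symbols, and Ctgf was used for Ccn2. Among its symbols, 238 stand on more than 1 identifier. Positions of the genes named come from the GENCODE annotation of GRCm38.

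Cells with at least 200 detected genes and at most 20% mitochondrial counts were kept, which left 4616 of 4694 cells. Scrublet, run through scanpy 1.11.5, marked 11 of these (0.238%) as doublets, and 4605 cells remained. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were taken, and a graph of 15 neighbours was clustered with the Leiden method at resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, Python 3.11.15). A cluster took the name of a cell type from markers of 17 types fixed before the data were examined. At least 3 markers had to be present in at least 20% of its cells and at 2 times the lower quartile of the clusters, and markers of another type could not outnumber its own among its 10 leading genes. This scoring was set after the data were seen, as the second of 2 tried. Clusters that missed it stayed unnamed and are called by leading genes.

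With 1 sample or 1 pooled matrix per group no replicates can be compared, so no test was run and no p-value is given. Counts were summed over the cells of a cluster and expressed as CPM, the count scaled to a total of 1000000 UMIs per cluster, with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Levels carry exact Poisson intervals, ratios conditional binomial intervals and shares exact Clopper-Pearson intervals, all at 95%. These intervals cover counting error only, not the spread between mice. A share of 0 is given with the limit that 3 counts of the total would set. Because gene names exist for 1 matrix, 5 comparisons of clusters within that matrix were made in place of the planned ones. The alternatives were run in full for 3 of them. The other 2 set the Saa1-led and the Ly6d-led against the Adh1-led hepatocyte-like cluster. For these, the naming of genes was repeated with an offset of 5 CPM and with a summed count of at least 10. Genes of the Ly6d-led cluster, which held 66 cells, are not described, because redrawn clusters did not keep it apart. These comparisons and their pairs were chosen after the data were seen. Genes with a summed count of at least 30 and at least 50 CPM on either side were ranked by log2 of the ratio of CPM with an offset of 20 CPM added to each side. The 10 highest and 10 lowest were named for the comparisons of mesothelial-like cells and 5 on each side for the Gpnmb-led against the Clec4f-led cluster and for hepatocyte-like clusters, with Clu and Lrp2 always named. Mitochondrial, ribosomal, immunoglobulin, haemoglobin, Gm- and Rik-named, Malat1, Neat1, Xist and Y-linked genes were left out, as were markers of other types and the 50 genes highest in hepatocyte-like cells. The rule was fixed before the data were examined, and its use between clusters was decided afterwards. The collagen-led cluster has no fixed name, and its ranking left out the markers of all types but the mesothelial type.

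A gene that helps to draw a cluster will differ between clusters by construction. Genes were therefore split at random into a pair of sets, cells were reclustered on each, and each named gene was measured again between clusters drawn without its own set. This was done where the redrawn cluster shared at least 50% of cells with the original. For the mesothelial-like and collagen-led clusters the share was 93.2% to 98.5%. Genes ranked highest or lowest on nearly the same cells tend to keep their direction there, so the remeasured ratio does not check how they were selected. For 25 gene lists fixed beforehand (458 genes), the median log2 ratio of the measured members was set against 10000 random lists of the same size matched on mean expression in 20 bins, and its percentile is given as a description of these cells. A member counts as at least 2-fold higher or lower by the ratio with the offset. Among the list members with the largest changes, 1 is not reported here. On simulated counts, the intervals held the true ratio for 95.8%, 95.5% and 95.6% of unchanged genes in the comparisons of the collagen-led with the mesothelial-like cluster, of mesothelial-like with other cells, and of the Gpnmb-led with the Clec4f-led cluster (3354, 3156 and 2974 genes). In each, all 50 genes at each of the 2-fold, 4-fold, 0.5-fold and 0.25-fold changes came out in the right direction. Of 200 unchanged lists, 3%, 2% and 3% fell in the outer 5%. The simulated counts were drawn from 1 pooled profile, without clustering, shared regulation of genes or spread between cells or mice. These rates therefore check the calculation and not how percentiles behave between real clusters.

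Shares of cells with a UMI and genes per cell were also taken after thinning each cell to 1000 UMIs, and no cell was shallower. Free RNA, released by broken cells and captured with intact ones, was judged from T-cell-like and neutrophil-like cells, with plasma-cell-like cells added for hepatocyte transcripts. The free-RNA profile that was subtracted came from erythroid-like, T-cell-like, B-cell-like and neutrophil-like cells together. It covered Clu, Lrp2 and genes at least 10 times higher in hepatocyte-like cells than in those cells. Alternatives fixed beforehand were a stricter cell filter (500 genes, 10% mitochondrial counts), no doublet removal, resolutions of 0.5 and 2.0, scaling by the median of ratios, subtraction of a free-RNA profile, the mean of per-cell CPM, an offset of 5 CPM, a summed count of at least 10, and thinning to 500 UMIs. Added after seeing the data were clustering without Clu, Lrp2 and the list genes, removal of the 5% of cells with the highest doublet scores, and clustering on the set of genes without the gene measured. In the first of these, list genes that are also naming markers stayed in the clustering. A value counted as moved when it left the 95% interval of the value reported, which for a list is the interval of the median over its members. Figures were drawn with matplotlib 3.10.9.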

Results

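To examine how clusterin, a secreted chaperone, and its endocytic receptor LRP2 (megalin) relate to liver scarring, liver cells from wild-type mice given CCl4 for 0, 2 or 4 weeks and from mice labelled CluKO given recombinant human clusterin with CCl4, for a time the labels do not give, were profiled one by one. The wild-type matrices held 20215 cells at 0 weeks, 7739 at 2 weeks and 15133 at 4 weeks, with 102125170, 53387027 and 79364101 UMIs in total. The matrix labelled CluKO, which pools 6 samples, held 4694 cells and 28912707 UMIs. Median UMIs per cell were 4009, 5070, 4093 and 4803.5 in the same order, and median detected genes were 1747, 2072, 1904 and 1809.5. With every cell thinned to 1000 UMIs, the median was 661 genes (quartiles 626 and 689) at 0 weeks, 671 (616 and 704) at 2 weeks, 685 (652 and 712) at 4 weeks and 628 (572 and 669) in the matrix labelled CluKO. The 10 most abundant rows held 7.52%, 9.11%, 8.97% and 11.3% of the counts. Each wild-type group is 1 sample, the 6 pooled samples cannot be separated, and the smallest cell held 2348 UMIs.

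Clu, the gene named in the knockout label, was counted in the matrix labelled CluKO. Clu (ENSMUSG00000022037, GRCm38 chromosome 14, 65968483 to 65981547, plus strand) gave 13740 UMIs there, a level of 480.0 CPM (95% interval 472 to 488), with a UMI in 31.8% of the 4605 cells kept. Its level was 1468 CPM (1425 to 1513) in mesothelial-like cells, which line the liver surface, and 1985 CPM (1936 to 2034) in hepatocyte-like cells. In T-cell-like and neutrophil-like cells, taken as background, it was 22.6 CPM (16.5 to 30.2). A Clu UMI was found in 98.8% of 325 mesothelial-like cells (96.9 to 99.7, median 8029 UMIs per cell), in 70.8% of 691 hepatocyte-like cells (67.2 to 74.1, median 3430) and in 8.79% of the 387 background cells (6.16 to 12.1, median 4139). After thinning to 1000 UMIs the shares were 72.6%, 42.7% and 2.58%. Clu counts run against the label, so the samples are called the matrix labelled CluKO. A tag at the 3' end outside the deleted part of the gene would check nothing, and the position of the deletion is not given in the sources used here.

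Among hepatocyte-like cells, the liver's metabolic cells, Clu was measured by cluster. It stood at 389 CPM (362 to 417) in the cluster led by Adh1, an alcohol dehydrogenase, and at 1421 CPM (1337 to 1509) in the cluster led by Saa1, an acute-phase serum protein. A group of 66 cells held 4472 of the 6324 hepatocyte-like Clu UMIs, at 10459 CPM. Clu is a leading gene of that group, so its level describes how it was drawn. The order of the Adh1-led and Saa1-led clusters depended on where these 66 cells fell. Where a separate cluster held most of them, the Adh1-led cluster stayed lower. It stood at 286 against 1418 CPM at resolution 2.0 and at 394 against 1396 CPM with the stricter cell filter. Without doublet removal the values were 392 and 1418 CPM, and without the 5% highest doublet scores 397 and 1230 CPM. At resolution 0.5 all 66 joined the Adh1-led cluster, which then stood at 2163 CPM against 1395 CPM in the Saa1-led cluster, and clustered without Clu and the list genes the values were 2159 and 1405 CPM. Between clusters drawn without Clu's set of genes the log2 ratio of the Saa1-led to the Adh1-led cluster was -0.57, against 1.82 as first drawn. The redrawn Adh1-led cluster there held 546 cells, all 66 among them.

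To locate the receptor, Lrp2 (ENSMUSG00000027070, chromosome 2, 69424340 to 69586065, minus strand) was counted in each cluster. Of 398 Lrp2 UMIs, 395 (99.2%, 97.8 to 99.8) lay in the mesothelial-like cluster and in a collagen-led cluster with mesothelial markers, and 3 lay in 3 of the 4077 other cells. The level was 78.1 CPM (68.3 to 88.9) in mesothelial-like cells and 116 CPM (99.0 to 135) in the collagen-led cluster. An Lrp2 UMI was found in 41.8% of mesothelial-like cells (36.4 to 47.4) and 44.3% of collagen-led cells (37.4 to 51.5, median 6070 UMIs), or 8.62% and 13.8% at 1000 UMIs per cell, against 0.258% of the background cells. It was seen in 0 of 691 hepatocyte-like cells, which allows a share of up to 0.434%, and in 0 of 822 macrophage/monocyte-like cells, which allows up to 0.365%. In endothelial-like cells the count was 0 of 23, which allows up to 13.0%. These limits hold for cells with a UMI and not for cells expressing the gene, since at 3430 UMIs, the median hepatocyte-like depth, a cell with Lrp2 transcripts can give no UMI.

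Partners of the receptor were measured in the same clusters. Dab2, the adaptor that links LRP2 to clathrin coats, stood at 268 CPM in mesothelial-like cells, 3.70-fold (3.39 to 4.02) above all cells outside both clusters. Lrpap1, the chaperone that escorts LRP2 to the surface, stood at 288 CPM, 2.12-fold higher (1.97 to 2.29). Lrp1, a related receptor found in many cell types, stood at 441 CPM and was 2.90-fold lower (2.75 to 3.07) than in the other cells. Cubn, the co-receptor cubilin, gave 2 UMIs in each cluster, and Amn, its membrane anchor, gave 0, so no level is given at this depth.

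**Figure D1:**
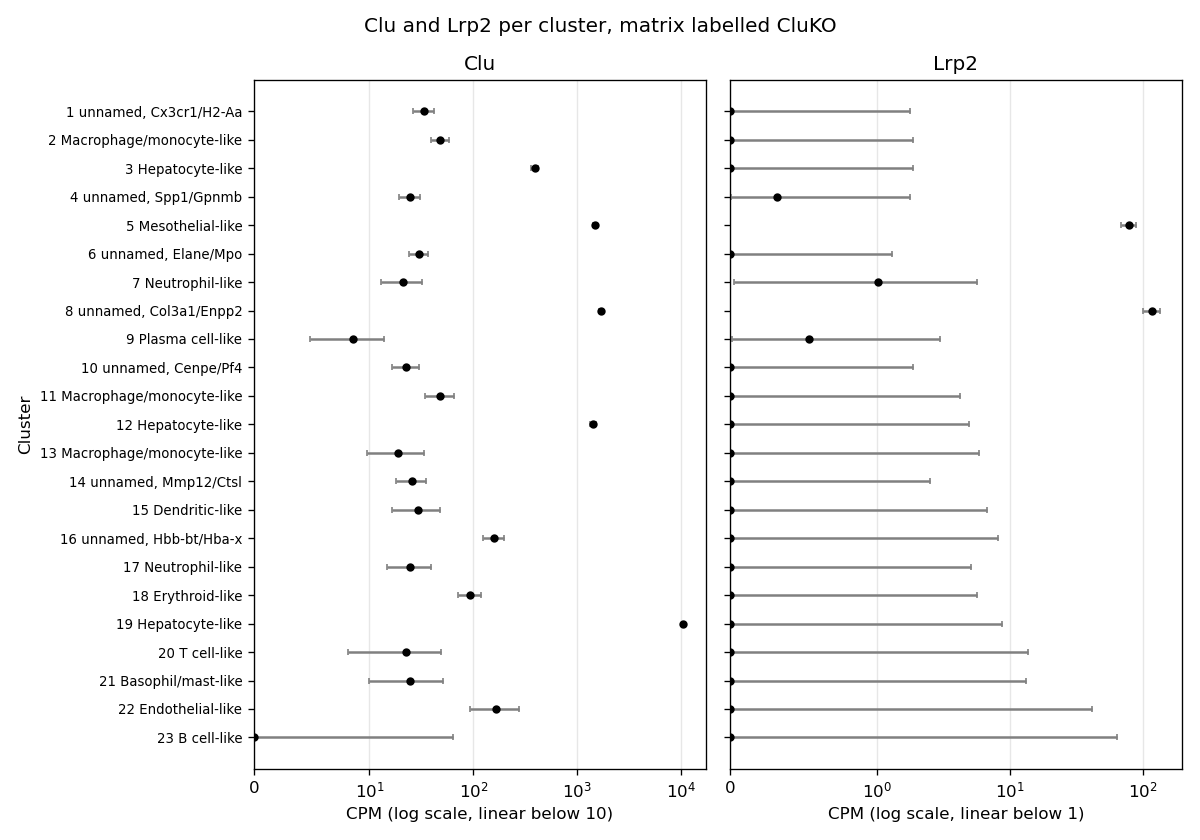
Clu (left) and Lrp2 (right) in CPM of each cluster's summed UMIs, on a log axis that turns linear near 0, for the 23 clusters of the matrix labelled CluKO, with points at the level and bars for the 95% Poisson interval of counting error. Lrp2 stands at 78.1 and 116 CPM in clusters 5 (mesothelial-like) and 8 (collagen-led) and near 0 elsewhere, whereas Clu is also high in the hepatocyte-like clusters 3, 12 and 19.

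The 4605 kept cells of the matrix labelled CluKO formed 23 clusters, of which 16 took a name from the fixed markers. Macrophage/monocyte-like cells made up 17.9% (16.8 to 19.0), but 28.5% at resolution 2.0 and 30.3% when clustered without the list genes, so the share depends on how clusters were drawn beyond its counting interval. Hepatocyte-like cells made up 15.0% (14.0 to 16.1), neutrophil-like cells 7.19% (6.46 to 7.97) and mesothelial-like cells 7.06% (6.33 to 7.84). Plasma-cell-like cells made up 4.19% (3.63 to 4.81), dendritic-like cells 2.91% (2.44 to 3.44), erythroid-like cells 2.02% (1.63 to 2.47), T-cell-like cells 1.22% (0.920 to 1.58) and basophil/mast-like cells 1.17% (0.882 to 1.53). Endothelial-like cells were 0.499% (0.317 to 0.748) and B-cell-like cells 0.326% (0.182 to 0.537). The 7 unnamed clusters held 1868 cells (40.6%). They were led by Cx3cr1 and H2-Aa (479 cells), Spp1 and Gpnmb (429), Elane and Mpo (299), Col3a1 and Enpp2 (203), Cenpe and Pf4 (191), Mmp12 and Ctsl (143) and Hbb-bt (124). Macrophage/monocyte was the best-scoring type of the clusters led by Cx3cr1, Cenpe and Mmp12, with 8 of 12 markers each. It was also that of the cluster led by Spp1, with 7 of 12. The share of 17.9% leaves these cells out, so it is not the share of all macrophages. No cluster was named for stellate cells or fibroblasts, the main collagen-producing cells of the liver. These are shares of the cells captured after enzymatic dissociation, red cell lysis and pooling, whose effect on them was not measured.

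Both clusters with Lrp2 carried fibrillar collagen, and UMIs of Col1a1, Col1a2 and Col3a1 occurred together in 98.0% of collagen-led and 67.1% of mesothelial-like cells. To describe how they differed, the collagen-led cluster (203 cells, 4.41% of cells, 3.83 to 5.04) was compared with the mesothelial-like cluster (325 cells). Col3a1, Col1a2 and Col1a1, which encode the fibrillar collagens of scar tissue, were 5.88-fold (5.63 to 6.14), 5.53-fold (5.26 to 5.81) and 5.15-fold (4.87 to 5.44) higher, with Col3a1 at 5569 against 947 CPM. Slpi, a secreted protease inhibitor, was 4.45-fold lower (4.34 to 4.56), Gpc3, a cell-surface proteoglycan, 5.54-fold lower (4.73 to 6.54), and the mesothelial surface protein Msln 2.98-fold lower (2.75 to 3.22). The collagens lead the collagen-led cluster, and Slpi and Msln lead the mesothelial-like cluster, so their ratios describe how these clusters were drawn. Wt1, a transcription factor of the mesothelium, was 1.20-fold higher (1.07 to 1.35). Clu and Lrp2 were 1.15-fold (1.09 to 1.21) and 1.49-fold (1.21 to 1.82) higher.

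The gene ranked highest by log2 ratio with the offset was Enpp2 (chromosome 15, 54838901 to 54952892), which encodes autotaxin, the secreted enzyme that makes lysophosphatidic acid. It was 148-fold higher (94.2 to 246), with a log2 ratio of 5.20 and of 5.24 between clusters drawn without its set of genes. Cxcl13 (chromosome 5, 95956951 to 95961068), a chemokine that attracts B cells, was 56.7-fold higher (39.2 to 85.2) at 559 against 9.85 CPM, with log2 ratios of 4.28 and 4.25. The other 8 highest were Col6a5 (3.68, 3.12 between redrawn clusters), Ly6a (3.03, 3.10), Fndc1 (2.96, 2.95), Ifi205 (2.95, 2.84), Spon2 (2.79, 2.60), the growth factor Fgf1 (2.76, 2.78), the proteoglycan Vcan (2.69, 2.58) and Serpinb2 (2.67, 2.70). Myl7 (chromosome 11, 5896637 to 5898782), known as the atrial myosin light chain, was 84.6-fold lower (48.3 to 164), with log2 ratios of -4.69 and -4.77. Angptl7 was 43.8-fold lower (29.1 to 69.2), Alcam, an adhesion molecule, 20.3-fold lower (15.7 to 26.7), and Id1, a target of BMP signalling, 7.07-fold lower (5.89 to 8.55). AU021092 (-3.60), Bst1 (-3.46), Enpp6 (-3.04), Vnn1 (-3.04), Cpe (-2.89) and Ppfibp2 (-2.72) were the others of the 10 lowest.

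**Figure D2:**
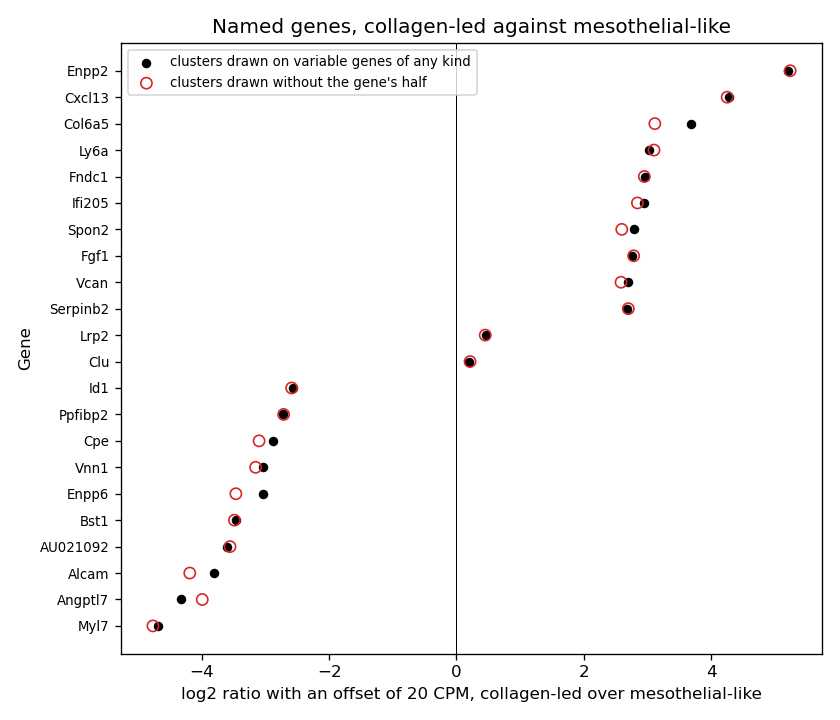
Log2 ratio with an offset of 20 CPM, collagen-led over mesothelial-like cluster, for the 10 highest and 10 lowest genes and for Clu and Lrp2, with filled points for the clusters as reported and open circles for clusters drawn without the set of genes that held the gene. The filled and open points lie on the same side of 0 for each gene, from 5.20 and 5.24 for Enpp2 to -4.69 and -4.77 for Myl7.

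The 29 measured members of the list of fibrillar collagens and matrix had a median log2 ratio of 0.59, above all 10000 random lists (percentile 100), with 7 at least 2-fold higher, Lum (34.7-fold, 17.1 to 82.0) among them, and 2 at least 2-fold lower, Timp1 (2.52-fold lower, 2.36 to 2.70) among them. When cells were clustered without the list genes the median was 0.57, but the 5 matrix genes that are stellate and fibroblast markers stayed in that clustering. Collagens lead the cluster, so a matrix list above random lists follows in part from how it was drawn. The mesenchymal-transition list, which shares 5 genes with the matrix list, had a median of 0.77 over 17 members (percentile 100), and stellate activation 0.34 over 20 (99.98), with Igfbp3 7.73-fold (6.43 to 9.33) and Lgals1 4.96-fold (4.79 to 5.15) higher. The mesothelial-identity list, of which 11 of 25 genes are also mesothelial markers used for naming, had a median of -0.51 (percentile 0; -0.52 clustered without list genes), with 10 members at least 2-fold lower and 0 at least 2-fold higher. Those 11 genes and 2 cholangiocyte markers of the list stayed in the clustering that gave -0.52. Stellate quiescence stood at -0.14 over 9 members (6.49), and the TGF-beta response at 0.13 over 19 (86.31). Of the stellate markers, the intermediate filament Des stood at 76.7 CPM (63.0 to 92.5) in collagen-led and 8.83 CPM (5.77 to 12.9) in mesothelial-like cells. Pdgfrb, a receptor of stellate cells, stood at 11.3 CPM (6.43 to 18.3) and 0.679 CPM (0.0823 to 2.45), and Lrat, the enzyme that stores vitamin A, gave 10 and 2 UMIs.

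Endocytic genes differed little between these clusters. The 18 measured members of the lipoprotein-receptor endocytosis list had a median of 0.074 (percentile 72.07), and 0 of them differed 2-fold. Lrp1 was 1.45-fold higher (1.33 to 1.58), and Dab2 and Lrpap1 were 1.39-fold (1.21 to 1.61) and 1.38-fold (1.21 to 1.59) lower. Inflammatory lists differed in direction, though the intervals of the acute-phase and the chemokine and cytokine medians spanned 0. The complement list had a median of -0.34 over 16 members (0.01), with C4b, a complement component, 2.15-fold lower, and the acute-phase list -0.24 over 14 (0.13), with Lcn2 3.38-fold (2.94 to 3.91) and Saa3 2.42-fold (2.38 to 2.46) lower. The interferon list had a median of 0.39 over 17 (99.99), with Ifit3 8.62-fold higher (5.53 to 13.9), and MHC class II 0.57 over 6 (99.89). Chemokines and cytokines had a median of -0.15 over 14 (2.04). Cxcl13, Cxcl12 (12.0-fold, 6.58 to 23.5) and Il6 (4.25-fold, 2.86 to 6.40) were the 3 members at least 2-fold higher, and the adhesion molecule Vcam1 (5.03-fold, 4.26 to 5.97) was the 1 at least 2-fold lower.

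The list of genes induced by dissociation had a median of 0.44 over 20 members (percentile 100), with the stress transcription factor Atf3 2.65-fold higher (2.36 to 2.98), and the unfolded-protein list 0.25 over 16 (98.92). Cell cycle stood at 0.24 over 24 (99.49), lipid synthesis and storage at 0.29 over 16 (99.85), oxidative stress at -0.026 over 16 (27.09) and p53 and apoptosis at -0.11 over 12 (8.05). Lists named for other cell types or states were measured as well. The lipid-associated macrophage list had a median of 0.43 (99.98), Kupffer identity -0.46 (0), sinusoidal identity -0.50 (0.04), capillarisation 0.47 (99.87), bile duct reaction -0.80 (0.13), pericentral hepatocyte 0.014 (44.36) and periportal hepatocyte -0.37 (0.22). Kupffer identity turned to 0.14 without the 5% highest doublet scores, and sinusoidal identity to 0.054 with a summed count of at least 10, so no direction is read from either. Intervals of the median over members also spanned 0 for capillarisation (-0.27 to 3.03), bile duct reaction (-1.63 to 0.43), periportal hepatocyte (-0.56 to 0.23) and cell cycle (-0.036 to 0.40). The same held for stellate activation (-0.0043 to 1.06), stellate quiescence (-0.61 to 1.75) and the TGF-beta response (-0.50 to 0.53). It also held for the acute-phase (-0.97 to 0.092) and chemokine (-0.82 to 1.20) lists, and for endocytosis, oxidative stress, p53 and pericentral hepatocyte. These values compare a pair of clusters in 1 pooled sample and carry no check between mice.

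**Figure D3:**
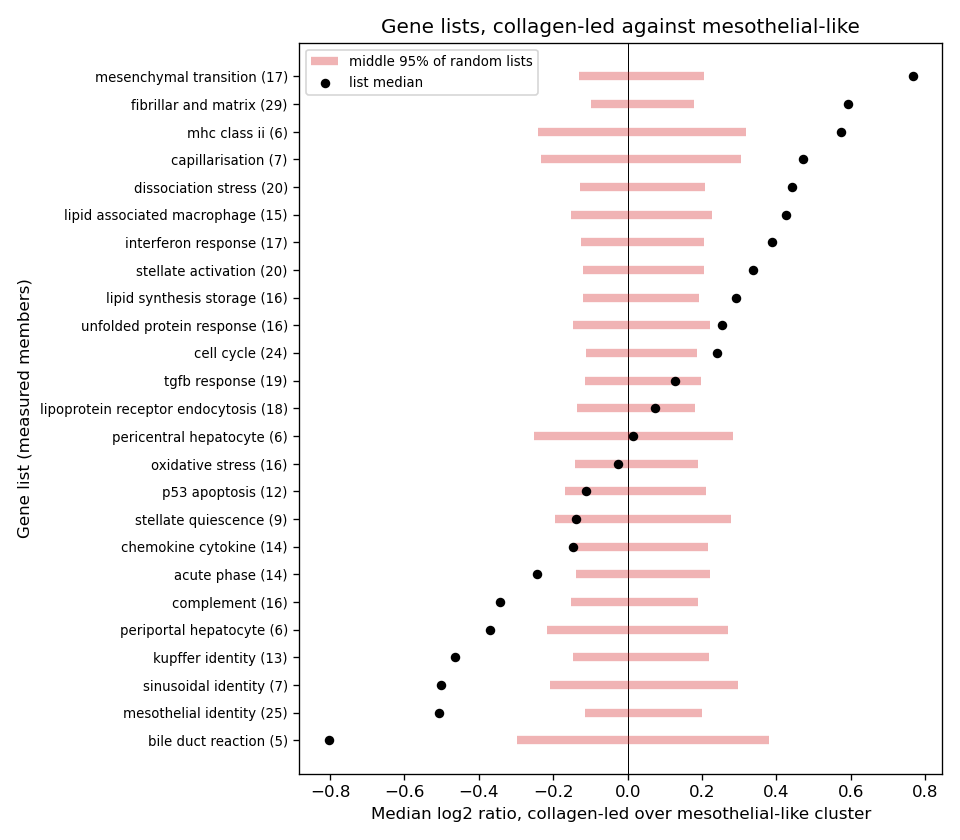
Median log2 ratio of each gene list, collagen-led over mesothelial-like cluster, with the number of measured members in parentheses and a band for the middle 95% of 10000 random lists matched on size and mean expression. The mesenchymal-transition (0.77) and matrix (0.59) lists lie above their bands and the mesothelial-identity list (-0.51) below its own, whereas lipoprotein-receptor endocytosis (0.074) lies within it.

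To set mesothelial-like cells beside the rest of the liver, they were compared with the 4077 cells outside both clusters. Saa3 (chromosome 7, 46711998 to 46715700), an acute-phase serum amyloid, was 340-fold higher (325 to 356) at 25943 against 76.3 CPM, with log2 ratios of 8.07 and of 7.87 between redrawn clusters. The complement component C3 (chromosome 17, 57203970 to 57228136) was 83.7-fold higher (80.5 to 87.0) at 9807 CPM, with log2 ratios of 6.16 and 6.14. Timp1, an inhibitor of matrix proteases, was 338-fold (284 to 406) and the matrix glycoprotein Sparc 164-fold (151 to 180) higher. Serpinh1, the collagen chaperone, was 239-fold higher (206 to 279). The binding proteins of insulin-like growth factors Igfbp5, Igfbp6 and Igfbp7 were 318-fold (273 to 372), 181-fold (162 to 203) and 115-fold (107 to 124) higher. Clu was 5.07-fold higher (4.88 to 5.27), and Lrp2 632-fold (213 to 3085), a ratio that rests on 3 UMIs in the other cells. Upk3b and Msln, also among the 10 highest, are naming markers. The size of these ratios depended on the clustering. At resolution 2.0 the mesothelial-like cluster kept 243 of its 325 cells, a further cluster of 82 cells that also took the name counted among the other cells, and the log2 ratios fell to 6.39 for Saa3, 4.64 (from 6.44) for Sparc, 3.34 (from 6.39) for Igfbp5, 3.61 (from 6.18) for Igfbp6, 4.91 (from 6.20) for Igfbp7, 4.51 (from 6.17) for Timp1, 4.47 for C3 and 4.48 (from 6.02) for Serpinh1.

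The 10 lowest included Mmp12, the macrophage elastase (124-fold lower, 80.3 to 203), Elane, the neutrophil elastase (69.0-fold, 48.3 to 102), Gpnmb (61.0-fold) and Tyrobp, an adaptor of myeloid receptors (27.8-fold, 24.6 to 31.6). The others were Prss34, Lpl, Ctss, Lcp1, C1qc and Fcer1g, from 69.9-fold to 26.9-fold lower. Of 28 measured matrix genes 24 were at least 2-fold higher and 0 at least 2-fold lower (median log2 3.54, percentile 100), and the proteoglycan Dcn was 214-fold higher (197 to 233). Of 18 complement genes 9 were at least 2-fold higher, such as the C1 inhibitor Serping1 (56.0-fold, 51.9 to 60.6), and 5 at least 2-fold lower, such as C1qb (28.6-fold lower, 25.3 to 32.5), with a median of 1.35 (100). The chemokine and cytokine list went both ways, with 8 of 23 at least 2-fold higher, 7 at least 2-fold lower and a median of -0.17 (3.13). Ccl2, which attracts monocytes, was 21.2-fold (19.6 to 23.0) and Cxcl1, which attracts neutrophils, 35.6-fold (31.3 to 40.7) higher, and Ccl6 was 22.1-fold (18.1 to 27.2) and Ccl9 18.0-fold (12.8 to 26.2) lower. The acute-phase list, which holds Saa3, had 5 of 18 members at least 2-fold higher and 10 at least 2-fold lower (-1.13, 0). The dissociation list was higher, with 12 of 20 at least 2-fold (1.36, 99.97), and the endocytosis list stood at -0.053 over 20 members (34.02). The median of all genes was shifted by 0.15 on the log2 scale, and relative to it MHC class II (-1.59, 0) and cell cycle (-0.47, 0.13) were lower. The other cells are a mixture, so these ratios depend on its makeup.

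The cluster led by Gpnmb and Spp1 (429 cells) met 7 of 12 macrophage markers but stayed unnamed, because markers of another type outnumbered these among its 10 leading genes. It was set against the cluster led by Clec4f and Marco (472 cells), a named macrophage cluster that bears markers of Kupffer cells, the resident macrophages of the liver. Fabp5, a fatty-acid binding protein, was 187-fold higher (122 to 303), with a log2 ratio of 6.03 and of 6.14 between redrawn clusters, and the endosomal protein Cd63 was 84.5-fold higher (65.5 to 111; 5.67 and 6.03). At resolution 0.5, where these clusters held 573 and 652 cells, the log2 ratios were 4.81 for Fabp5 and 3.39 for Cd63. Spp1, or osteopontin, was 145-fold higher (115 to 185; 6.56 and 6.77). Timd4, a receptor for dying cells on resident macrophages, was 346-fold lower (175 to 802; -5.32 and -5.29), and the scavenger receptor Marco 481-fold lower (320 to 759; -7.01 and -6.83). Clu stood at 24.4 CPM (19.3 to 30.5) in the Gpnmb-led and 47.9 CPM (38.8 to 58.6) in the Clec4f-led cluster, beside 22.6 CPM in the background cells, and Lrp2 gave 1 and 0 UMIs.

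Of 16 genes of lipid-associated macrophages, 14 were at least 2-fold higher (median log2 2.85, percentile 100), and Cd9, a tetraspanin membrane protein, was 8.45-fold higher (7.01 to 10.3). Of 17 Kupffer-identity genes, 6 of them naming markers, 13 were at least 2-fold lower (-2.41, 0). Clustered without the list genes, these medians were 3.10 and -2.31. List genes that are naming markers stayed in that clustering. Its Gpnmb-led cluster held 474 cells, with 312 of the original 429 among them. The pair was picked by leading genes such as Gpnmb, Trem2 and Spp1 against Clec4f and Marco. The direction and percentiles of both lists therefore follow in part from that choice. Interferon genes were lower, with 11 of 18 at least 2-fold (-1.17, 0), as for Irf7 (9.95-fold lower, 8.33 to 12.0) and Ifit3 (16.3-fold lower, 11.3 to 24.2). Complement genes were lower in 7 of 14 (-1.01, 0) and MHC class II in 5 of 6 (-1.40, 0.34). Lipid synthesis and storage split, with Fabp4 39.6-fold higher (28.7 to 56.4) and Scd1, the stearoyl-CoA desaturase, 11.6-fold lower (8.95 to 15.2), at a median of -0.17 (31.47). The median of all genes was shifted by -0.31. Gpnmb, Lgals1, Atp6v0d2, Fcna, Cd163 and C6 were also among the 5 highest and 5 lowest, but the redrawn clusters shared too few cells to measure them apart from the clustering, and Clec4f names its cluster.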

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

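Clustering without the list genes, removal of the 5% highest doublet scores and clusters drawn without a gene's own set were chosen after the data were seen, and the other alternatives were fixed before the data were examined. No paired analysis was possible because the barcodes of the 6 samples labelled CluKO carry no sample name and no test was made between groups. Leaving out each of these samples in turn was not run for that reason, and alternatives for the comparisons with wild-type matrices were not run because the files used here do not pair those rows with gene names. The share of mesothelial-like cells was 5.28% at resolution 2.0, where a further cluster of 82 cells took the name and was not counted, and 6.31% without the 5% highest doublet scores, where hepatocyte-like cells made up 16.6%. Macrophage/monocyte-like cells made up 28.5% at resolution 2.0 and 30.3% when clustered without list genes, where clusters led by Ms4a7 and Apoe (348 cells) and by Cx3cr1 and Apoe (565 cells) took that name. Weighting each cell equally gave Clu 1621 CPM in mesothelial-like and 1268 CPM in hepatocyte-like cells, and Lrp2 95.3 CPM in mesothelial-like and 137 CPM in collagen-led cells. Thinning to 1000 and 500 UMIs left an Lrp2 UMI in 8.62% and 3.38% of mesothelial-like cells and in 13.8% and 6.40% of collagen-led cells, as fewer UMIs per cell must. The log2 ratio of Clu, collagen-led over mesothelial-like, was 0.11 when scaled by the median of ratios and 0.11 with cells weighted equally, against 0.20. Genes per cell at 500 UMIs were 379, 383 and 388 at 0, 2 and 4 weeks and 362 in the matrix labelled CluKO. Between the Gpnmb-led and Clec4f-led clusters, the medians of the acute-phase list (-0.27) and the p53 list (-0.23) reversed to 0.038 and 0.084 under the median of ratios, which removes the shift of all genes. The cause of the other moves was not tested. Over all alternatives run, collagen-led over mesothelial-like, the log2 ratio of Lrp2 ranged from 0.37 to 0.54, the matrix list from 0.51 to 0.65 and mesothelial identity from -0.59 to -0.38. In the same comparison Kupffer identity ranged from -0.70 to 0.14 and sinusoidal identity from -0.63 to 0.054, and stellate quiescence, pericentral hepatocyte and oxidative stress also changed sign. Gpnmb-led over Clec4f-led, lipid-associated macrophages ranged from 2.27 to 3.16 and Kupffer identity from -2.46 to -2.10, while lipid synthesis and storage, among other lists, changed sign (-0.53 to 0.14). Counting each single gene or list beyond these main values under each alternative, 1161 values stayed within the interval and 138 moved, 53 of them with an offset of 5 CPM. Mesothelial-like over other cells, Saa3 ranged from 6.39 to 8.32 and Igfbp5 from 3.34 to 7.54, lowest at resolution 2.0, and Gpnmb-led over Clec4f-led, Cd63 ranged from 3.39 to 6.18, lowest at resolution 0.5. The endocytosis list, collagen-led over mesothelial-like, ranged from -0.013 to 0.16. Of the named genes, 14 of 20, 13 of 20 and 8 of 10 were named again with an offset of 5 CPM, and 20, 20 and 10 with a summed count of at least 10. For the Saa1-led against the Adh1-led hepatocyte-like cluster, 5 of 10 and 10 of 10 were named again. The number of cells limits the statements on endothelial-like and B-cell-like cells most, with 23 and 15 cells.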

Other observations

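All tests in this part were chosen after the result they bear on was seen. Mki67, a protein of dividing nuclei, stood at 1014 CPM (939 to 1094) in erythroid-like cells, at 719 CPM (689 to 751) in the cluster led by Elane and Mpo, and at 742 CPM (705 to 781) in the cluster led by Cenpe and Pf4. Mesothelial-like cells had 168 CPM of Mki67 (154 to 184) and collagen-led cells 264 CPM (238 to 292), against 15.2 CPM (11.2 to 20.2) in the unnamed Gpnmb-led cluster and 52.5 CPM (42.9 to 63.6) in the Clec4f-led macrophages. Elane, a granule protease made by immature granulocytes, stood at 5762 CPM in its cluster, beside 4860 CPM of Mpo and 3866 CPM of Prtn3. Klf1, a transcription factor of red cell precursors, stood at 692 CPM in erythroid-like cells. Il6, a cytokine that drives the acute-phase response, stood at 156 CPM (113 to 209) in basophil/mast-like cells.

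Hepatocyte-like cells fell into separate clusters. Whether these are cell states or differ by sample cannot be told, since the pooled samples cannot be separated. Against the Adh1-led cluster, the Saa1-led cluster was 8.92-fold (7.63 to 10.5) higher in Pzp, 8.91-fold (7.45 to 10.7) in Cp, or ceruloplasmin, and 8.31-fold (7.34 to 9.42) in Kng1, each a secreted plasma protein. The enzyme Cyp3a11 (8.07-fold, 6.96 to 9.39) and Vtn (7.51-fold, 6.52 to 8.67) were the others of the 5 highest. Nupr1, a stress-induced gene, was 7.44-fold lower (4.28 to 14.2) and Jun 5.79-fold lower (3.31 to 11.1) in the Saa1-led cluster. Trib3, ranked lowest, was 29.0-fold lower (7.89 to 241) on 2 UMIs. Gadd45g (6.84-fold, 3.74 to 13.9) and Anxa2 (4.39-fold, 3.54 to 5.50) were the others of the 5 lowest. Between clusters drawn without the gene's own set, the log2 ratios went from 2.94 to 2.76 for Pzp, from 2.87 to 1.53 for Cp, from 2.91 to 2.78 for Kng1, from -1.99 to -1.30 for Nupr1 and from -1.69 to -0.73 for Jun. Clu changed sign, from 1.82 to -0.57, where the redrawn Adh1-led cluster took in all 66 cells of the Ly6d-led cluster. Mitochondrial counts were 0.0921% of UMIs in the median hepatocyte-like cell, against 1.54% over all kept cells and 2.28% in mesothelial-like cells.

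The presence of Clu UMIs in the matrix labelled CluKO was weighed first. Free RNA would give every class a like level, and Clu in mesothelial-like cells was 65.1-fold (48.5 to 89.3) that of T-cell-like and neutrophil-like cells, which argues against it. A mixture of cells with and without the transcript would leave many mesothelial-like cells without Clu, and 1.23% (4 cells, 0.336 to 3.12) had none, which argues against a mixture within that class, though its cells could come from few of the 6 pooled samples. In hepatocyte-like cells a mixture stays open, since 42.2% (37.5 to 46.9) of Adh1-led cells had no Clu UMI against 23.7% expected from depth, an excess at percentile 92.59 among 742 genes of like level. A transcript kept by the knockout allele, or samples under a wrong label, may explain the counts and stay open, since 0 wild-type matrices have named rows to compare with and the place of the deletion is not given in the sources used here, while the recombinant human protein brings no mouse transcript.

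The collagen-led cluster carried mesothelial markers, with at least 3 of them and all 3 fibrillar collagens in 94.1% of its cells, against 67.1% of mesothelial-like cells and 0 of 387 T-cell-like and neutrophil-like cells. Doublets of mesothelial-like cells with collagen-producing cells would need such producers as single cells, and cells with at least 5 UMIs of the 3 collagens and no mesothelial marker UMI numbered 3, a count equal to 1.48% (0.306 to 4.26) of the cluster's cell number, and the cluster's median UMIs per cell were 0.756 times those of mesothelial-like cells, which argues against doublets. Free RNA was argued against by summed mesothelial markers at 114-fold (92.7 to 142) the background level, 5200 against 45.6 CPM. Whether these are mesothelial cells with high collagen or stellate cells or fibroblasts with mesothelial markers stays open, since all 11 mesothelial markers were met, but also 8 of 14 stellate and fibroblast markers (6 of 14 in the mesothelial-like cluster), with Des at 76.7 against 8.83 CPM in mesothelial-like cells. No biological explanation was tested, because the design names no group that separates these clusters.

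Hepatocyte transcripts were counted in Clec4f-led macrophages. For Alb free RNA stays open, since macrophages held 3.22-fold (2.91 to 3.57) the UMIs per cell of T-cell-like, neutrophil-like and plasma-cell-like cells together, 2.97 against 0.922, but 1.47-fold (1.27 to 1.70) those of the neutrophil-like cluster 17, which held 2.03. Against background clusters 7, 9 and 20 alone the ratios were 3.65 (3.12 to 4.29), 5.62 (4.60 to 6.95) and 5.74 (3.98 to 8.60). Cluster 17 met 7 of 10 neutrophil markers but also 8 of 12 macrophage/monocyte markers, so it is a doubtful background for macrophages. Clusters 1, 4, 10, 11 and 14, whose best-scoring type was macrophage/monocyte, held 1.88 to 2.43 Alb UMIs per cell. Macrophage/monocyte-like cluster 13 held 0.296, mesothelial-like cells 0.735 and collagen-led cells 0.901. For Fabp1, Ttr and Apoa1 together the ratio was 0.939 (0.869 to 1.01), as free RNA would give, but the sum joins genes that differ. Apoa1 stood at 0.602 against 0.409 UMIs per cell. It was 1.84-fold (1.40 to 2.46) the level of plasma-cell-like cluster 9 and 1.21-fold (0.907 to 1.65) that of cluster 17. Doublets with hepatocytes would raise Fabp1 with Alb, and Fabp1 was at 0.746 times (0.665 to 0.837) the level of those cells. Hepatocyte RNA from 1 source in every macrophage would raise the other 9 hepatocyte markers with Alb, and for 7 of them, or 6 against cluster 17 alone, the excess per cell lay below 50% of what that needs by more than counting error, so what raises Alb stays open. Cps1 and Tat were not among these. They stood at 0.157 and 0.360 UMIs per cell, against 0.0207 and 0.105 in the pooled background cells and 0.0270 and 0.135 in cluster 17.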
